A study of Rattus norvegicus with 21 samples.

How the data were processed

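RNA sequencing data from 21 libraries of rat PC12 cells were analysed, 3 for each of 7 groups: vehicle, and the water and the ethanol extract of Jakyakgamcho-tang at 4, 20 and 100 µg/mL. Per the labels' protocols, total RNA was made into messenger RNA libraries with a directional kit that keeps the strand of origin. The labels give the vehicle group both as vehicle and as an untreated sample. Samples were grouped by their treatment labels, and replicate numbers were those of the labels.

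The deposited values were expected counts per gene as RSEM estimates them, which need not be whole, together with an effective length per gene and library in bases, per the file headers. The counts were not normalized. RSEM 1.3.3 is named in the submitters' processing notes. The aligner's version, the genome build, the annotation and the strand setting were not given in the sources used here. Each table held 32883 Ensembl rat gene IDs, and 3281 of them (9.98%) had a count that was not whole in at least 1 library. RSEM divides reads that fit several genes, so genes with a close copy depend on that division.

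The ID column carries no gene names. A table of 47357 RefSeq rat genes of the GRCr8 assembly was searched for the IDs, and 0 of them paired with a symbol. The 30 gene lists fixed before the data were examined (stress, sterol, neuronal, cell cycle and cell type marker genes among them), the listed transcription factors and the rule that named only genes with a symbol could therefore not be applied. The planned camera and fry tests of those lists were not run. Instead, IDs were named by the rest of the rule for the comparison of high-dose ethanol extract with vehicle: adjusted p under 0.05, a mean of at least 1 CPM over the 6 libraries, and every library of 1 group above every library of the other. Among the 271 higher and 242 lower genes that passed, the 2 with the largest log2 change each way were taken. No other IDs were printed, even where a comparison called few genes.

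Expected counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) with its default filter on low counts and TMM normalization. One model with 1 coefficient per group was fitted to all 21 libraries, 13550 genes were tested, and 13 comparisons were made. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors of log2 fold changes were the absolute change divided by the square root of the F statistic. CPM values used TMM-scaled totals, and log2 CPM used a prior count of 2. The fragment length of a library was the median of gene length less effective length over genes of at least 1000 bases.

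Total expected counts ranged from 8344416 to 28420922 per library. The edgeR test was tested on simulated data drawn from the means and totals of the real libraries, with 50 genes changed at each of 4 sizes. Only genes with a mean of at least 1 CPM were changed. Each gene had the same dispersion in every simulated library, while the real libraries differed in spread, so the results need not hold for them. For high-dose ethanol extract against vehicle, the test recovered 10, 52, 84 and 100% of genes changed 1.25, 1.5, 2 and 4-fold with 21 libraries (13463 genes, 6 false among 129 calls). With 18 libraries it recovered 70, 92, 96 and 100% (13626 genes, 9 false among 188 calls). The covariance step was tested on simulated effects as well. These used genes of at least 1 CPM on average and the estimated dispersions divided by 4. A true covariance of 0.04 came back as 0.0413 and one of 0 as 0.000894, over 12259 genes. How the step performs at the full dispersion and with low-count genes was not tested.

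Counts of 2 libraries of the same group were compared by chi-square to look for a library present more than once. Over the 21 pairs, chi-square per degree of freedom was 3.06 to 148, so no pair agreed within sampling noise.

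Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, effective length offsets, the replicate number as a block, a fit of only the groups compared, and leaving out each library of the groups compared. Alternatives added after the data were seen were leaving out the 3 libraries that stood apart, limma-voom with a weight per library, and fragment length as a covariate with 21 and with 18 libraries. The replicate block with 18 libraries and a comparison of high with low dose averaged over both extracts were also added then. For comparisons against the same vehicle libraries, unchanged groups were simulated 20 times from the fitted means and dispersions. Other splits of the libraries were refitted for each comparison, at most 100 per comparison.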

Results

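PC12 cells, a line derived from a rat adrenal pheochromocytoma that makes catecholamines and is widely used as a neuronal cell model, were profiled by sequencing of messenger RNA libraries. The cells received vehicle or 1 of 2 extracts of Jakyakgamcho-tang (JGT), an East Asian herbal formula of peony root and licorice root. The extracts were made with water or with ethanol. Each was given at a low dose of 4 µg/mL, a medium dose of 20 µg/mL or a high dose of 100 µg/mL. The 21 libraries fell into 7 groups of 3. Total expected counts were 19918513 to 23781470 in the vehicle libraries, 18398186 to 28420922 in the water extract libraries and 8344416 to 23528245 in the ethanol extract libraries. After the filter on low counts, 13550 genes were tested. The stated purpose of the series was to find transcription factors behind expression changes linked to JGT. The comparisons that bear on it are each extract against vehicle, the extracts against each other, and high against low dose.

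Genes are given by Ensembl rat ID, because the count tables list IDs and do not pair them with names. Only 2 IDs that were higher and 2 that were lower in the high-dose ethanol group are named, and their chromosomal positions were not analysed here. Nothing in the labels says that the 3 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

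A set of 3 ethanol libraries stood apart from the other 18, namely replicates 2 and 3 of the medium-dose group and replicate 1 of the low-dose group. Over the genes tested, the median absolute deviation from the median library was 0.229, 0.34 and 0.207 log2 units in these libraries and 0.052 to 0.158 in the other 18. Their 10 most abundant genes took 5.87, 5.74 and 5.54% of all counts, against 6.97 to 8.33% in the others. Their fragment lengths were 202.5, 178.7 and 193.8 bases, against 205.3 to 240.8 bases. Their total expected counts were 11345609, 14918515 and 8344416. Because 1 model was fitted to all libraries, the number of genes called in each comparison is given with all 21 libraries and again with the other 18. The second set was added after the data were seen. With 18 libraries the medium-dose ethanol group rests on 1 library, whose spread is assumed to equal that of the other groups.

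**Figure D1:**
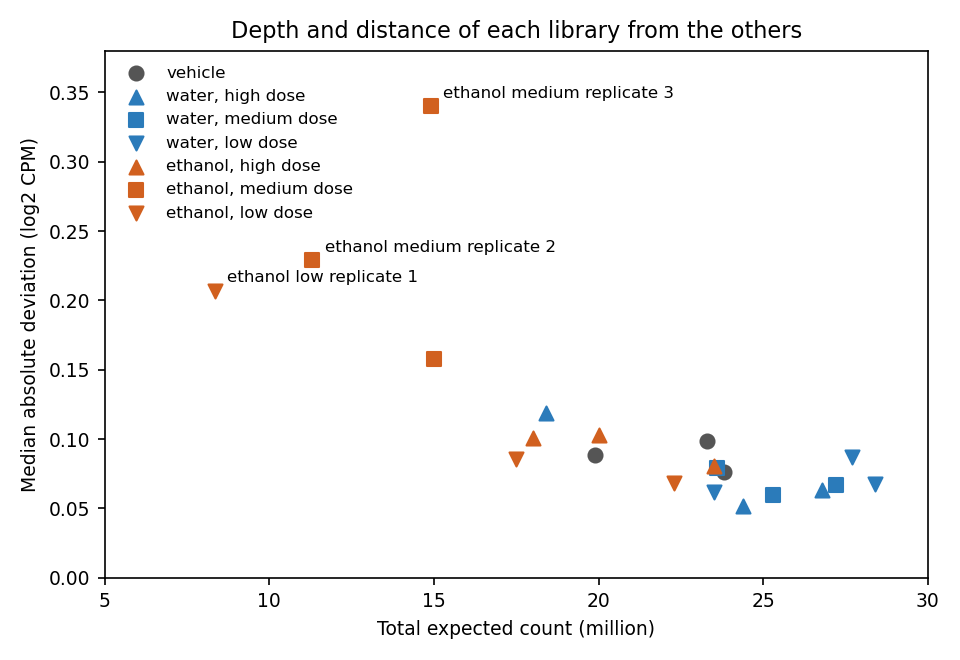
Total expected count of each library, on the horizontal axis, against its median absolute deviation from the median library in log2 CPM (vertical axis), 1 point per library, coloured by vehicle, water or ethanol extract and shaped by dose. The 3 labelled ethanol libraries deviate by 0.207 to 0.34, above the 0.052 to 0.158 of the other 18.

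In the high-dose ethanol group, ENSRNOG00000046379.2 stood at 72 ± 12.4 CPM (counts scaled to a common library total; SD, n = 3), against 2.02 ± 3.49 CPM (SD, n = 3) in vehicle. Its log2 fold change was 5.27 ± 1.02 (SE), with an adjusted p of 0.0104 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. ENSRNOG00000009115.7 rose from 0.561 ± 0.092 to 2.23 ± 0.206 CPM (SD, n = 3 each), a log2 change of 1.98 ± 0.389 (SE; edgeR adjusted p = 0.00664). It was a short, low-count gene of 228 bases, against fragment lengths of 178.7 to 240.8 bases, so its counts depend on fragment length. It had 11 to 15 counts per vehicle library and 43 to 48 per high-dose ethanol library. ENSRNOG00000005724.5 fell from 27.7 ± 3.18 to 10.7 ± 3.3 CPM (SD, n = 3 each), with a log2 change of -1.37 ± 0.275 (SE; edgeR adjusted p = 0.00955). ENSRNOG00000026705.5 fell from 1.59 ± 0.314 to 0.609 ± 0.0842 CPM (SD, n = 3 each), with a log2 change of -1.38 ± 0.268 (SE; edgeR adjusted p = 0.00613). The naming rule required every high-dose library to lie on the same side of every vehicle library. In total, 285 genes were higher and 246 lower than in vehicle at the high dose of ethanol extract, with a median absolute log2 change of 0.496 among them. Of these, 43 were higher and 15 lower by at least 2-fold. With 18 libraries, 1543 were higher and 1583 lower, 81 and 35 of them by at least 2-fold, and all 531 genes from the fit of 21 libraries were among them. Their median lengths were 2092 bases for the higher and 2752 bases for the lower genes, against 2160 bases over all genes tested.

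ENSRNOG00000046379.2 had counts that were not whole in 16 libraries and counts of 0 in the other 5. ENSRNOG00000005724.5 had counts that were not whole in all 21 libraries. RSEM splits reads between genes of similar sequence, so the levels of both IDs are uncertain. The vehicle level of ENSRNOG00000046379.2 came from replicate 3 alone, with 118 counts, while the other 2 vehicle libraries had 0. The size of its change is therefore not fixed: limma-voom gave a log2 change of 9.15, and without vehicle replicate 3 the fitted value of 13.57 was against libraries at 0. Its call was lost with DESeq2 (adjusted p = 0.102) and without vehicle replicate 1 (edgeR adjusted p = 0.0593), and over all alternatives its adjusted p ranged from 0.000896 to 0.102. The call of ENSRNOG00000005724.5 was lost without vehicle replicate 3 (edgeR adjusted p = 0.054) and without high-dose ethanol replicate 1 (edgeR adjusted p = 0.0553), with a range of 8.07e-05 to 0.0553.

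**Figure D2:**
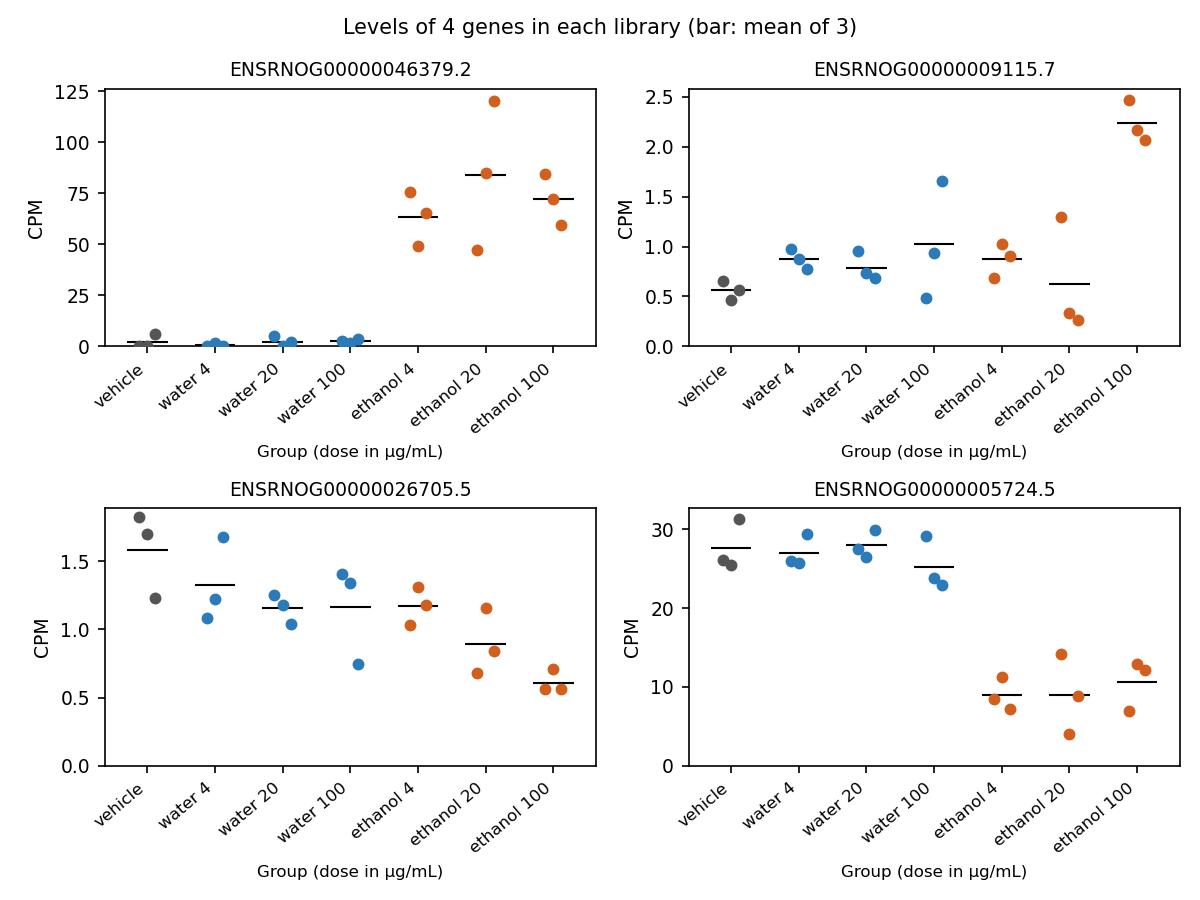
CPM (vertical axis) of 4 genes in the 7 groups (horizontal axis, with the dose in µg/mL), 1 point per library and a bar at the mean of 3. ENSRNOG00000046379.2 is at 47.4 to 120 CPM in the 9 ethanol libraries and at 0 to 6.05 CPM in the other 12, while ENSRNOG00000005724.5 is lower in the ethanol groups.

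At the low and medium doses of ethanol extract, ENSRNOG00000046379.2 stood at 63.4 ± 13.4 and 84.1 ± 36.4 CPM (SD, n = 3 each), with log2 changes from vehicle of 5.08 ± 1.03 and 5.50 ± 1.03 (SE; edgeR adjusted p = 0.0188 and 0.00833). ENSRNOG00000005724.5 stood at 8.97 ± 2.05 and 9.01 ± 5.04 CPM (SD, n = 3 each), with log2 changes of -1.62 ± 0.287 and -1.60 ± 0.286 (SE; edgeR adjusted p = 0.0068 and 0.00606). ENSRNOG00000009115.7 did not pass at these doses (edgeR adjusted p = 0.463 and 0.816), at 0.873 ± 0.17 and 0.627 ± 0.576 CPM (SD, n = 3 each). ENSRNOG00000026705.5 did not pass at the low dose (edgeR adjusted p = 0.417), and at the medium dose its log2 change was -0.85 ± 0.27 (SE; edgeR adjusted p = 0.0448). With 18 libraries, where 1 medium-dose library is left, the medium-dose log2 changes were 4.71 ± 1.04 for ENSRNOG00000046379.2, -0.96 ± 0.299 for ENSRNOG00000005724.5, 1.199 ± 0.459 for ENSRNOG00000009115.7 and -1.22 ± 0.431 for ENSRNOG00000026705.5 (SE; edgeR adjusted p = 0.00633, 0.0352, 0.0573 and 0.0392). At the low dose 218 genes were higher and 133 lower than in vehicle, and at the medium dose 1038 were higher and 769 lower.

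With the fragment length covariate and 18 libraries, the low dose gave 378 genes, which held 175 of the 351 genes from the fit of 21 libraries. With 18 libraries and no covariate, the low dose gave 657 higher and 677 lower genes, which held 339 of the 351. Their median lengths were 1883 bases for the higher and 2772 bases for the lower ones. The medium dose gave 1483 higher and 1943 lower genes from 1 library against 3, which held 705 of the earlier 1807, and 116 of the 1807 had the opposite sign. The genes called with 18 libraries differed in length, with a median of 1513 bases for the higher and 3725 bases for the lower ones, against 2160 bases over all genes tested. In the 1 medium-dose library left, the correlation across genes between gene length and deviation was -0.395. In a fit of only the 6 libraries compared, with all 3 medium-dose libraries, the medium dose gave 0 genes. With limma-voom and 21 libraries the medium dose gave 963 higher and 1151 lower genes, so the balance of higher and lower turned.

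In cells given the water extract, none of the 4 named IDs passed the threshold against vehicle at any dose. ENSRNOG00000046379.2 stood at 0.56 to 2.81 CPM over the 3 group means, with edgeR adjusted p from 0.836 to 1. ENSRNOG00000005724.5 stood at 25.3 to 28 CPM over the group means, with edgeR adjusted p from 0.992 to 1. ENSRNOG00000009115.7 had its highest water mean at the high dose, 1.03 ± 0.593 CPM (SD, n = 3), with a log2 change of 0.89 ± 0.413 (SE; edgeR adjusted p = 0.747, and 0.105 with 18 libraries). ENSRNOG00000026705.5 stood at 1.16 ± 0.363 CPM (SD, n = 3) at the high dose, with an edgeR adjusted p of 0.823. The low dose gave 31 higher and 19 lower genes, the medium dose 1 higher and 0 lower, and the high dose 6 higher and 3 lower. At the high dose these were 4 and 1 with DESeq2 size factors and 4 and 0 with effective length offsets. At an unadjusted p under 0.05 these comparisons gave 1344, 424 and 892 of 13550 genes, or 9.92, 3.13 and 6.58%. With 18 libraries they gave 3446, 1410 and 2666 of 13759.

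With 18 libraries, the low dose of water extract gave 709 higher and 735 lower genes, the medium dose 25 and 14, and the high dose 272 and 324. All genes called with 21 libraries in these comparisons were among them. Their median absolute log2 changes were 0.263, 0.391 and 0.273. Their median lengths were 2198, 1811 and 2136 bases for the higher and 2848, 2567 and 3570 bases for the lower genes, against 2160 bases over all genes tested. The low dose thus gave more genes than the 5-fold higher medium dose. In a direct comparison of the low and medium doses with 18 libraries, added after the data were seen, 45 genes were higher and 69 lower at the low dose by edgeR's quasi-likelihood test.

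**Figure D3:**
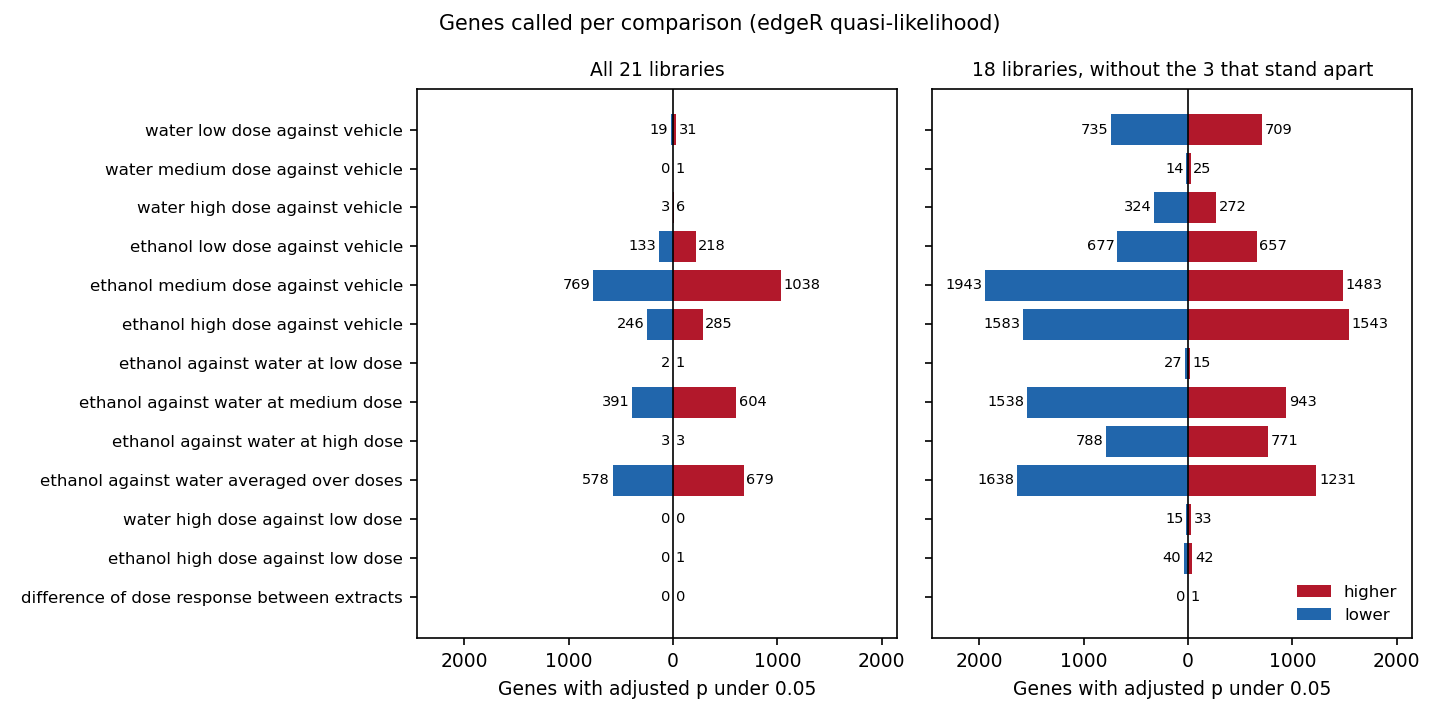
Number of genes higher (right of 0) and lower (left of 0) at an edgeR adjusted p under 0.05 in each of the 13 comparisons, with all 21 libraries (left panel) and with 18 libraries (right panel). High-dose ethanol extract against vehicle goes from 285 higher and 246 lower genes to 1543 and 1583.

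The extracts were compared with each other at the same dose, without the vehicle libraries. ENSRNOG00000046379.2 was higher with ethanol than with water extract averaged over the doses, by a log2 difference of 5.52 ± 0.602 (SE; edgeR adjusted p = 0.000417), and every one of the 9 ethanol libraries lay above every one of the 9 water libraries. ENSRNOG00000005724.5 was lower by -1.48 ± 0.163 (SE; edgeR adjusted p = 0.000184), again with no overlap between the 9 and 9 libraries. The size of the first difference is not fixed, since it was 7.74 without water low replicate 2 and 7.11 with limma-voom. For ENSRNOG00000009115.7 the averaged log2 difference was 0.27 ± 0.238 (SE; edgeR adjusted p = 0.469), and with 18 libraries it was 0.64 ± 0.206 (SE; edgeR adjusted p = 0.0271). With the fragment length covariate and 18 libraries it did not pass (edgeR adjusted p = 0.0814), and over the alternatives its adjusted p ranged from 0.0271 to 0.781. For ENSRNOG00000026705.5 it was -0.49 ± 0.155 (SE; edgeR adjusted p = 0.0549), and with 18 libraries -0.59 ± 0.197 (SE; edgeR adjusted p = 0.0343), but with the covariate and 18 libraries it did not pass (edgeR adjusted p = 0.0802), and the adjusted p ranged from 0.0273 to 0.309 over the alternatives. At the high dose alone, none of the 4 passed, with edgeR adjusted p of 0.107 for ENSRNOG00000046379.2, 0.115 for ENSRNOG00000005724.5, 0.249 for ENSRNOG00000009115.7 and 0.202 for ENSRNOG00000026705.5. With 18 libraries all 4 passed at the high dose, with log2 differences of 4.70 ± 0.756, -1.22 ± 0.199, 1.08 ± 0.265 and -0.92 ± 0.282 (SE) and edgeR adjusted p of 0.00369, 0.00359, 0.0109 and 0.0365 in that order.

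Across all genes, ethanol against water gave 1 higher and 2 lower genes at the low dose (0 and 2 with effective length offsets), 604 and 391 at the medium dose, and 3 and 3 at the high dose. Averaged over doses, 679 genes were higher and 578 lower with the ethanol extract. limma-voom turned the balance, with 633 higher and 750 lower averaged over doses and 595 higher and 715 lower at the medium dose. With 18 libraries these counts were 15 and 27 at the low dose, 943 and 1538 at the medium dose, 771 and 788 at the high dose, and 1231 and 1638 averaged over doses. The averaged calls with 18 libraries had a median length of 1621 bases for the higher and 3267 bases for the lower genes, against 2160 bases over all genes tested. Of the 1257 genes called on average over doses, 928 were called again with 18 libraries. The ethanol libraries had shorter fragments, at 209.2 ± 16.1 bases (SD, n = 9) against 226.4 ± 6.65 bases (SD, n = 9) in the water libraries. With fragment length as a covariate and all 21 libraries, the medium-dose comparison gave 0 genes and the average over doses gave 40. With the covariate and 18 libraries, the low dose gave 4 genes, the medium dose 2192, the high dose 1451 and the average 1841.

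For high against low dose within an extract, none of the 4 named IDs passed in either extract. ENSRNOG00000009115.7 had a log2 difference of 1.303 ± 0.384 (SE; edgeR adjusted p = 0.666) within the ethanol extract, and ENSRNOG00000026705.5 of -0.96 ± 0.288 (SE; edgeR adjusted p = 0.673). For ENSRNOG00000046379.2 and ENSRNOG00000005724.5 the ethanol differences were 0.19 ± 0.763 and 0.26 ± 0.295 (SE; edgeR adjusted p = 1 for each). The water extract gave 0 genes by edgeR, with 494 at an unadjusted p under 0.05, while DESeq2 gave 11 and limma-voom 0. The ethanol extract gave 1 higher gene, and the difference of dose response between extracts gave 0 genes by edgeR, with 425 at an unadjusted p under 0.05, while DESeq2 gave 4 and limma-voom 0. With 18 libraries the counts were 33 higher and 15 lower for water, 42 and 40 for ethanol, and 1 higher gene for the difference between extracts. At an unadjusted p under 0.05, 1981 genes for water and 1145 for the difference passed with 18 libraries.

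Both extracts were set against the same 3 vehicle libraries, so their changes share chance values. At the high dose, all 6 genes that were higher with water extract were also higher with ethanol extract, and 2 of the 3 lower genes were also lower. Independent lists of these sizes would share 0.126 and 0.0545 genes, and groups simulated without any effect against the same controls shared 0.1 calls on average and 1 at most in 10 simulations. Few genes are called where nothing changes, so this does not show how many called genes the shared controls alone would make agree. With 18 libraries, 219 of 272 higher and 239 of 324 lower genes were shared, against 30.5 and 37.3 for independent lists, and 0 had opposite directions. Across genes, which are not independent replicates, the covariance of the log2 fold changes of water and ethanol extract was 0.0748, against 0.0243 in the simulated unchanged groups, a difference of 0.0505. Their correlation was 0.524, against a simulated 0.486, and 68.3% of genes had the same sign, against 66.5%. The correlations differed far less than the covariances, so the simulated fold changes spread less than the real ones. The covariance difference therefore does not by itself show a shared effect. With 18 libraries the covariance was 0.0801, against a simulated 0.0269, the correlation 0.508 against 0.489, and the same-sign share 68.5% against 66.7%. At the low dose, with 18 libraries, the covariance was 0.0801 against a simulated 0.0245, the correlation 0.498 against 0.442 and the same-sign share 75.8% against 64.9%, and leaving out single libraries was not tested there. With 21 libraries the excesses in correlation and in same-sign share turned when 1 library was left out. The correlation was 0.597 against a simulated 0.619 without vehicle replicate 1, 0.597 against 0.617 without vehicle replicate 2 and 0.422 against 0.43 without water high replicate 2. The same-sign share was 68.6% against 70.7% without vehicle replicate 1 and 68.7% against 70.1% without vehicle replicate 3. Without vehicle replicate 1, 2 or 3 the covariance rose from 0.0748 to 0.114, 0.113 and 0.126, against a simulated 0.0429, 0.0433 and 0.0415. It was 0.0784 to 0.0891 when a high-dose water or ethanol library was left out. A rise with fewer controls goes with chance values that both comparisons share, and not with an effect of the extracts. The 3 vehicle libraries are too few to be split into parts of 2, so part or all of the excess may come from the shared controls.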

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

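The tests of depth and the counts over other splits of the libraries were set before their results were seen. All the other tests of possible explanations below were chosen after. The comparisons of ethanol with water extract, limma-voom and leaving out single libraries were planned. Within a group, 3 libraries are too few for a test of a single outlying library, and no such test pooled over groups was run. A difference between the water and the ethanol extract, tested directly, drew attention to 4 counts and 2 IDs. Ethanol against water gave 3 genes at low dose, 995 at medium dose, 6 at high dose and 1257 averaged over doses. ENSRNOG00000046379.2 differed by 5.52 log2 units and ENSRNOG00000005724.5 by -1.48 averaged over doses. The first of these was 7.74 without water low replicate 2 and 7.11 with limma-voom.

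The first pattern is that 3 ethanol libraries stood apart, with a median deviation of at least 0.207 log2 units. Lower depth alone does not account for it: when each of the other 18 libraries was thinned to the lowest total, 8344416 counts, the highest deviation was 0.171. A trend over gene length does not account for it either, since with that trend removed the lowest of the 3 still deviated by 0.198 and the highest of the others by 0.129. An effect of the extract at the low dose would also move the other 2 low-dose ethanol libraries, and these deviated by at most 0.0857, under the 0.119 of the highest vehicle or water library. For the 2 medium-dose libraries such an effect and a technical difference cannot be told apart, because only 1 other library of that group is left. That library deviated by 0.158, but mainly in another direction. On the first principal component, the axis along which the libraries varied most, it lay at -6.4, against 50.11 and 73.86 for the 2. The vehicle libraries lay at -11.36 to -10.09 there and the water libraries at -11.22 to -6.708. The remaining medium-dose library was thus shifted only slightly towards the 2. On the second component it lay at -32.11, against 11.95 and 17.47 for the 2. Partial breakdown of the RNA may account for the shorter fragments of the 3 libraries and stays open.

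The second pattern is the difference between ethanol and water extract. At high dose the fragment lengths overlapped, at 213.6, 231.1 and 217 bases in ethanol and 216.6, 227.3 and 222.1 bases in water libraries. Shorter fragments therefore do not account for the difference there, and fragment length as a covariate had little to remove. Of 1559 genes called at high dose with 18 libraries, 1404 were still called with the covariate. The median difference was 0.253 log2 units before and 0.253 after (quartiles 0.201 to 0.34 after). Averaged over doses, of the 2869 genes called with 18 libraries 1765 were still called, with a median of 0.191 before and 0.187 after, so shorter fragments are not the whole account of these genes. In this average with 18 libraries, the medium dose rests on 1 library. Its fragments were not short, at 224.4 bases, but its deviation correlated with gene length by -0.395. Median lengths of the higher and lower calls were 1621 and 3267 bases averaged over doses and 1395 and 3753 bases at medium dose. They were 2664 and 1396 bases at low and 2281 and 2219 bases at high dose. The covariate does not address such a trend, so how many averaged calls reflect this library is open. For the counts with all 21 libraries fragment length stays open. At medium dose 0 of 995 were still called, with a median of 0.469 before and 0.232 after (quartiles 0.373 to 0.652 and 0.16 to 0.366) and a median standard error of 0.122 and 0.13, so these calls ended mainly with a smaller difference. Averaged over doses 31 of 1257 were still called, with a median of 0.257 before and 0.158 after (quartiles 0.2 to 0.356 and 0.104 to 0.266) and a median standard error of 0.0647 and 0.0738, and fragment length and extract cannot be told apart there, because 3 ethanol libraries have the shortest fragments. At low dose 4 of 42 were still called, the median went from 0.444 (quartiles 0.308 to 0.586) to 0.385 (0.281 to 0.587) and the median standard error from 0.077 to 0.0927, so most calls ended with a wider error and a smaller difference, and fragment length and extract cannot be told apart there. A handling difference unrelated to dose stays open and cannot be told apart from an effect of the extract. Over 1537 genes called for the mean of the low and high dose, the difference was 0.148 at low and 0.23 at high dose, and an exact permutation test of the 0.0802 between them gave a two-sided p of 0.065 (200 arrangements). The genes in which all 9 ethanol libraries lay outside the range of the other 12 numbered 77, against 0.083 by chance. A handling or culture difference between the extracts may also give such genes. They differed by 0.223 at low, 0.39 at medium (2 of its libraries stand apart) and 0.229 at high dose. These genes were chosen to differ at every dose, so their profile over dose decides nothing between handling and an effect of the extract.

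The third pattern is that the vehicle libraries differed from all treated libraries. In 281 of 12259 genes the 3 vehicle libraries lay outside the range of the other 18, against 18.4 by chance, and no other group had more than 150. The median shift of these genes from vehicle was 0.244 ± 0.043 log2 units (SD, n = 9) in water and 0.405 ± 0.099 (SD, n = 9) in ethanol libraries. The shift was larger in ethanol libraries (exact permutation p = 0.00075, two-sided, and 0.0075 with 18 libraries). These genes were chosen with every treated library beyond vehicle, which favours larger shifts in libraries that vary more. The ethanol libraries varied more, so vehicle handling alone is not excluded for the larger ethanol shift. For the shift common to both extracts, at least 0.195 in every treated group, vehicle handling and a shared effect of the extracts cannot be told apart, because there is 1 vehicle group. The high minus low dose difference was -0.018 log2 units (-0.05 to 0.03 when 1 library was left out), but these genes were chosen to differ at the low dose too, so an effect that grows with dose stays open.

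Other splits of the libraries were counted for each comparison. Each pair of groups has 10 splits, too few for a share under 0.05. In 8 of these comparisons, 1 split, the real one, gave its count and the highest other split gave 0: water low (50), medium (1) and high (9) against vehicle, ethanol low (351) and high (531) against vehicle, ethanol against water at low (3) and high (6) dose, and ethanol high against low dose (1). For water high against low dose the real count was 0 and all 10 splits gave 0. For ethanol medium against vehicle, 2 splits gave at least the real 1807, and the highest other, 2468, put ethanol medium replicates 2 and 3 with vehicle replicate 1. For ethanol against water at medium dose, 4 splits gave at least the real 995, and the highest other, 2137, put the same 2 libraries with water medium replicate 1. Both keep ethanol medium replicates 2 and 3 together. With 18 libraries, water low (1444), water high (596) and ethanol high (3126) against vehicle and ethanol against water at high dose (1559) had 0 in the highest other split. For ethanol against water averaged over doses, 1 of 100 splits, the real one with 1257, gave as many, and the highest other gave 1. This is the smallest share that 100 splits can give, so a chance split of these libraries is unlikely. For the difference of dose response the real count was 0, so all 100 splits gave at least as many by construction, the highest other gave 6, and nothing follows about chance.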

How the results depend on the processing

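The alternatives without the 3 libraries that stood apart, with library weights and with the fragment length covariate were chosen after the data were seen, and the others before. The main counts were, against vehicle, 50, 1 and 9 for water low, medium and high and 351, 1807 and 531 for ethanol. For ethanol against water they were 3, 995 and 6 at low, medium and high dose and 1257 averaged over doses. High against low dose gave 0 for water, 1 for ethanol and 0 for their difference. Median standard errors at high-dose ethanol against vehicle were 0.13 with 21 libraries and 0.0765 with 18. For ethanol medium against vehicle, 705 of the 1807 calls were kept with 18 libraries and 116 reversed. The covariance difference of 0.0505 moved by under 0.0108 with DESeq2 size factors and with 18 libraries. With 18 libraries it was 0.0542, or 0.0532 in a second set of simulations. The 0.0108 is the SD of the values with 1 library left out. All of those values were above 0.0505, so this SD is not a spread around it.

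Without the 3 libraries, the counts against vehicle were 1444, 39 and 596 for water low, medium and high and 1334, 3426 and 3126 for ethanol. Ethanol against water gave 42, 2481, 1559 and 2869 at low, medium and high dose and averaged. High against low dose gave 48 for water, 82 for ethanol and 1 for their difference. limma-voom with library weights, which keeps all 21 libraries, gave 1741, 99 and 1116 for water, 2308, 3951 and 3173 for ethanol, and 122, 3785, 1490 and 4247 for ethanol against water, with 118, 93 and 1 for the dose comparisons. In the fit of only the groups compared, water gave 1630, 127 and 427, and ethanol gave 128, 0 and 3140. There ethanol against water gave 0 at the medium dose, 780 at the high dose and 733 averaged, and high against low dose gave 6 for water and 3 for ethanol. DESeq2 gave 241, 8 and 69 for water, 725 and 798 for low and high ethanol, and 29, 2020, 157 and 1956 for ethanol against water, with 11, 25 and 4 for the dose comparisons. The cause of the difference between DESeq2 and edgeR was not tested. limma-voom gave 79 for water low, 5 for ethanol against water at low dose and 2 for ethanol high against low dose.

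With the fragment length covariate and 21 libraries, water gave 121, 4 and 21, ethanol medium gave 20, ethanol against water gave 0 at the medium dose, 41 at the high dose and 40 averaged, and ethanol high against low dose gave 0. With the covariate and 18 libraries, water gave 1380, 30 and 443, and ethanol medium and high gave 3375 and 2751. Ethanol low gave 378, against 1334 with 18 libraries and no covariate. Ethanol against water then gave 4 at the low, 2192 at the medium and 1451 at the high dose and 1841 averaged, against 42, 2481, 1559 and 2869 without the covariate, and the dose comparisons gave 27, 53 and 1. Water high against vehicle gave 5 with DESeq2 size factors, 5 with no filter and 4 with effective length offsets. Ethanol against water at medium dose gave 600 with no filter. The cause was not tested for these 4 counts. The higher calls were 53.7% of the main ethanol high calls and 54.6% with effective length offsets. Only counts of 9 or fewer had a share of higher calls that DESeq2 size factors or effective length offsets moved by over 10 percentage points. For water high it was 66.7% in the main test, 80% with DESeq2 size factors and 100% with effective length offsets, and for ethanol against water at low dose 33.3% became 0%. limma-voom gave 633 higher and 750 lower genes for ethanol against water averaged over doses, 595 and 715 at the medium dose, and 963 and 1151 for ethanol medium against vehicle, while in each of these the main test gave more higher than lower genes.

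Over all 21 libraries the labels' replicate numbers showed no clear pairing, but a batch shared by replicate number is not excluded. The deviations of same-numbered libraries from their group means correlated by 0.015 on average over 63 pairs (-0.17 to 0.25), 11 pairs were over 0.1, and 9 of 21 libraries correlated best with their own number. As a hint from the data only, the replicate block moved water high against vehicle from 9 to 15 and ethanol high against low dose from 1 to 0, and moved no other count by over 1.5 times. In number of genes it moved the medium-dose counts most, from 995 to 673 for ethanol against water and from 1807 to 1584 against vehicle. With the block and 18 libraries, water gave 1573, 71 and 740, ethanol 1414, 3267 and 3299, and ethanol against water 50, 2359, 1660 and 2980, with 66, 94 and 3 for the dose comparisons.

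Leaving out 1 library also left fewer libraries in the test. For water low, water high and ethanol low against vehicle, each of the 6 libraries moved the count by over 1.5 times. So did each library but the third for water medium, the second for ethanol medium and the third for ethanol high. For ethanol against water the exceptions were water low 2 and ethanol low 3 at low dose, ethanol medium 2 at medium dose, and water high 2 and 3 at high dose. For the average they were water low 1, water high 3, ethanol low 2 and 3, ethanol medium 2 and 3, and ethanol high 3. Counts ran from 7 (without vehicle replicate 3) to 24 (without water low replicate 3) for water low, from 0 (without vehicle replicate 2) to 3 (without water medium replicate 2) for water medium, and from 1 (without vehicle replicate 3) to 5 (without vehicle replicate 2) for water high. Ethanol low ran from 73 (without vehicle replicate 3) to 531 (without its replicate 3), and ethanol high from 162 (without its replicate 2) to 376 (without its replicate 3). Ethanol medium ran from 336 (without its replicate 3) to 6082 (without its replicate 1), and was 1934 without its replicate 2. Ethanol against water ran from 0 (without water low replicate 3) to 3 at the low dose and from 2 to 5 at the high dose. At the medium dose it ran from 1 (without water medium replicate 3) to 6005 (without ethanol medium replicate 1), with 27 without ethanol medium replicate 3. Averaged over doses it ran from 568 (without ethanol high replicate 1) to 4929 (without ethanol medium replicate 1). Ethanol high against low dose ran from 0 to 1. The covariance difference ran from 0.052 (without ethanol high replicate 1) to 0.085 (without vehicle replicate 3), and was 0.0708, 0.0698 and 0.0654 without vehicle replicates 1 and 2 and water high replicate 1.

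Of 290 combinations of a comparison and an alternative, 13 reversed the sign of a gene called in the main test, with 612 such reversals, counting a gene once per alternative. They were in ethanol medium against vehicle, ethanol against water at medium dose and ethanol against water averaged over doses. The log2 difference of ENSRNOG00000009115.7 between extracts averaged over doses, 0.27 in the main test and not called, was -0.16 with effective length offsets, which matter for a gene of 228 bases, and 0.10 with library weights (limma-voom adjusted p = 0.781). It ran from -0.10 (without ethanol medium replicate 1) to 0.44 (without water high replicate 3) when 1 library was left out, and the cause of that was not tested. It was 0.64 and called with 18 libraries (edgeR adjusted p = 0.0271), 0.64 and called with the block and 18 libraries (edgeR adjusted p = 0.0379). It was 0.64 and not called with the covariate and 18 libraries (edgeR adjusted p = 0.0814), and 0.67 and not called with the covariate and 21 libraries (edgeR adjusted p = 0.317). The 18-library call of ENSRNOG00000026705.5 was also lost with the covariate (log2 difference -0.61, edgeR adjusted p = 0.0802). The log2 changes of the 4 named IDs at high-dose ethanol kept their direction in all alternatives. The naming rule required no overlap between these libraries and vehicle, so that direction was largely set by the choice of IDs. Simulated 1.5-fold changes at high-dose ethanol were recovered for 52% of genes with 21 libraries and for 92% with 18, from the same libraries at the same depth. Depth as a limit was not tested apart from the spread. The planned gene list alternatives were not run, because no ID was paired with a symbol.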

Other observations

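The comparison below was chosen after each extract alone had given few genes for high against low dose. Averaged over both extracts, 5 genes were higher and 1 lower at the high than at the low dose by edgeR's quasi-likelihood test, and with 18 libraries 129 were higher and 99 lower, with median lengths of 2054 and 3475 bases against 2160 bases over all genes tested. The count of 6 was 52 with DESeq2, 46 with only the groups compared, 16 with the fragment length covariate and 311 with library weights. With 18 libraries it was 189 with the covariate and 248 with the replicate block. The median absolute log2 change was 0.451 among the 6 genes and 0.224 among the 228. The hypothesis that some genes change with dose on average over the extracts was tested by other splits of the libraries into high and low within each extract. With 21 libraries 1 of 100 splits, the real one, gave 6 genes and the highest other gave 0. With 18 libraries 1 of 100 gave 228 and the highest other gave 11. A share of 1 in 100 is the smallest that 100 splits can give. No allowance was made for choosing this comparison after the others, so chance is less likely but not excluded. A change in 1 extract alone can pass this comparison. Within each extract, high against low dose with 21 libraries gave 0 genes for water and 1 for ethanol. None of the 6 genes thus passed in water, and at most 1 passed in ethanol. Which of the 228 genes passed within an extract was not examined. None of the 4 named IDs was among these genes. The count was 2 without water high replicate 1, water high replicate 2, water low replicate 1, water low replicate 2 or ethanol high replicate 1, was 3 without water high replicate 3, ethanol high replicate 3, ethanol low replicate 2 or ethanol low replicate 3, and was 10 without ethanol low replicate 1.

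The water extract showed no steady rise with dose in the number of genes that differed from vehicle with 18 libraries, which was 1444 at 4 µg/mL, 39 at 20 µg/mL and 596 at 100 µg/mL. The median shift of the 281 genes that set vehicle apart was also lower at the medium dose. This shift comes from the same water and vehicle libraries as the counts and is no separate support for them. It was 0.285 at low, 0.195 at medium and 0.259 at high dose of water extract, and the libraries of the medium dose (0.181 to 0.204) did not overlap those of the low dose (0.249 to 0.32) or the high dose (0.252 to 0.262). With 3 against 3 libraries, chance gives no overlap in 10% of cases.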
